A study of Mus musculus with 12 samples.

How the data were processed

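RNA was measured in the hypothalamus of adult mice that carry Cre recombinase in cells with the long leptin receptor (LepRb) and a green fluorescent protein fused to the ribosomal protein L10a. In the Stat3KO mice the Stat3 gene was also floxed. Per the labels, a block with edges of 3 mm was taken from the ventral diencephalon caudal to the optic chiasm at the midpoint of the light cycle, and tissue of 5 to 8 mice was pooled. Tagged ribosomes were pulled down on beads, which gave the bead-bound RNA of LepRb cells, and the RNA left behind is the supernatant. Libraries were made with the TruSeq mRNA kit from RNA with an integrity number of at least 8 and read in 50 cycles, single end, on a HiSeq 2000 with 4 libraries per lane. The kit is not stated to keep the strand, so transcripts of overlapping genes on opposite strands cannot be told apart.

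The deposited table holds raw whole-number counts per gene, 1 column per library, which the authors did not normalise. Per the submitters' processing notes, reads were mapped with STAR 2.5.3a to mm10. The counting step, the annotation release and any filter are not given in the sources used here. The table has 52638 entries, of which 2 count the transgenes Cre and Gfp_L10a; how reads were assigned between the tagged L10a and the mouse gene is not stated. Gene names and coordinates were taken from GENCODE M21 on GRCm38, whose release may differ from the authors' own. It matched 52403 identifiers and left 233 unmatched, 147 entries share a symbol, and 18204 entries had a count of 0 in all 12 libraries. All columns were mapped to samples through the numbers in the sample descriptions, and 0 columns were left over.

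Total counts ranged from 20743217 to 41829907 per library. Pearson's r between replicates, across genes on the log2 scale, was 0.976 to 0.989 in Stat3KO bead-bound RNA, 0.986 to 0.991 in Stat3KO supernatant, 0.979 to 0.984 in Ctrl bead-bound RNA and 0.987 to 0.991 in Ctrl supernatant; genes are not independent replicates. Counts of libraries within a group were compared by a chi-square statistic per gene to look for libraries from 1 RNA sample, and no pair within a group was within sampling noise. Reads carry no molecular identifiers, so depth speaks to counting error only.

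The 12 libraries form 4 groups of 3 (genotype by fraction) from 6 pools of mice. Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, a quasi-likelihood fit, and Benjamini-Hochberg adjusted p under 0.05, 2-sided. The 6 comparisons were Stat3KO against Ctrl in bead-bound RNA and in supernatant, bead-bound against supernatant RNA in each genotype, the difference of the bead to supernatant ratio between genotypes, and that ratio averaged over both genotypes. The last 2 used all 12 libraries and the others only their 6. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are CPM (counts scaled to a common library size with TMM), with the SD over 3 libraries.

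Bead-bound and supernatant RNA of 1 number came from 1 pool, while the main fits did not use this pairing. Fits with the pool as a block were also made where fractions were compared. Between genotypes within a fraction the replicate number was the block instead. They are given beside a result, or with the processing, where they change it. The numbers do not pair pools of the 2 genotypes. No batch, date or lane is given for single libraries.

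Lists of genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Each was repeated with a correlation estimated from the data, and with fry, which asks whether a list moves on balance 1 way without comparing it with other genes. The 17 gene lists cover leptin and STAT3 targets, interferon-induced genes, the JAK-STAT pathway, neuropeptides, peptide processing and granules, hormone and peptide receptors, transmitter identity, hypothalamic transcription factors, immediate early genes, endoplasmic reticulum (ER) stress, cholesterol synthesis, inflammation, nuclear genes of oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear noncoding RNAs and sex-linked genes. The 14 marker lists cover neurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, mural cells, ependyma and tanycytes, meningeal fibroblasts, pituitary, choroid plexus, blood, thalamus, and striatum with cortex. Some genes stand in more than 1 list: Irf9 is both a leptin target and an interferon-induced gene, and Pomc is both a leptin target and a neuropeptide.

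The comparisons, tests, lists, other settings and the rule for naming genes were fixed before the data were examined. The rule names Stat3, Lepr, Agrp, Npy, Pomc, Cartpt, Socs3, Atf3, Serpina3n, Ghrh, Gal, Nts and the transgenes. For each comparison of genotypes it adds up to 12 genes higher and 12 lower, and for each comparison of fractions up to 8, with the largest change among genes that passed, had a mean log2 CPM of at least 1 and did not overlap between groups. From each list it adds up to 4 members that passed, or up to 2 with the smallest p where none did, and it leaves out clone and model names. Some genes that the rule covers are not reported here. Lists of interferon-induced GTPases, of MHC class I antigen presentation, of leukocyte markers and of glucocorticoid-responsive genes were added after the genes that changed most had been seen.

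The alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library totals alone, no filter on low counts, a filter of 10 CPM in 3 libraries, an adjusted p under 0.1, folds of at least 1.5 or 2, all 12 libraries in 1 fit, the block, and each library left out in turn. Fits on replicates 2 and 3 alone were added after replicate 1 of each group had been seen to stand apart. For lists, leaving out libraries was run in the bead-bound comparison of genotypes alone. The test was tried on simulated data in which known genes were changed, drawn without the pairing of pools. For a 2-fold change it called 55.2% of the changed genes in bead-bound RNA between genotypes and 76.1% in supernatant. Between fractions it called 53.7% in Ctrl and 52.2% in Stat3KO, and 31.3% for the difference of ratios. For a 4-fold change these were 90.9%, 90.9%, 84.8%, 87.9% and 81.8%. Unchanged genes were 10 of 111 calls in bead-bound RNA between genotypes and 11 of 151 in supernatant. They were 6 of 105 between fractions in each genotype, 6 of 82 for the difference of ratios and 12 of 154 for the averaged ratio.

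Reads could be shared between near-identical genes of the Gbp, Ifit3, H2-Q, Serpina3 and Tgtp families, so the split of counts among their members is uncertain. Exon counts were not analysed here.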

Results

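The data are RNA counts from the hypothalamus of mice labelled as Stat3 knockouts in LepRb cells (Stat3KO) and of controls (Ctrl). STAT3 is a transcription factor that the leptin receptor activates. RNA on the tagged ribosomes of LepRb cells (bead-bound) and RNA left after the pull-down (supernatant) were sequenced from 3 pools per genotype, which gave 4 groups of 3 libraries. Replicates 1, 2 and 3 held 34332749, 38570113 and 36510678 counts in Stat3KO bead-bound RNA and 38018639, 41829907 and 24552775 in Stat3KO supernatant. The Ctrl libraries held 24536698, 33060270 and 39445250 counts in bead-bound RNA and 20743217, 38056675 and 40433256 in supernatant. All values below rest on n = 3 pools per group.

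Stat3 (ENSMUSG00000004040; GRCm38 chromosome 11, 100885098 to 100939540), the targeted gene, was counted in every library. In replicates 1, 2 and 3 it stood at 114, 149 and 160 CPM in Stat3KO bead-bound RNA and at 144, 175 and 179 CPM in Ctrl bead-bound RNA. The supernatant levels were 54.5, 74.2 and 79.7 CPM in Stat3KO and 56.0, 65.1 and 59.6 CPM in Ctrl. The difference between genotypes was within the spread of the replicates in bead-bound RNA (log2 fold change -0.24, SE 0.160, adjusted p = 0.999) and in supernatant (0.20, SE 0.138, adjusted p = 0.878). The deposited counts cover the whole gene, so they do not show whether the floxed exons were lost, and the supernatant comes mostly from cells without Cre. Lepr, the leptin receptor gene, was at 11.5 ± 1.86 CPM (SD) in Stat3KO and 10.7 ± 4.20 CPM in Ctrl bead-bound RNA. The tagged ribosomal protein transcript, Gfp_L10a, was at 131 ± 42.2 and 131 ± 33.5 CPM, with log2 fold changes of -0.01 for it and -0.16 for Cre.

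The comparison of Stat3KO with Ctrl bead-bound RNA asks which transcripts of LepRb cells depend on STAT3. Pomc, which encodes the precursor of appetite-suppressing melanocortin peptides, fell from 521 ± 53.2 CPM in Ctrl to 127 ± 22.6 CPM in Stat3KO (log2 fold change -2.03, SE 0.171, adjusted p = 0.000166; ENSMUSG00000020660, chromosome 12, 3954951 to 3960642). Cartpt, the gene of another appetite-suppressing peptide, fell from 517 ± 76.7 to 175 ± 45.9 CPM (-1.56, SE 0.206, adjusted p = 0.0056; ENSMUSG00000021647, chromosome 13, 99898489 to 99901091). The genes of 2 peptides that drive feeding rose. Agrp went from 130 ± 9.49 to 463 ± 229 CPM (1.84, SE 0.289, adjusted p = 0.0198; ENSMUSG00000005705, chromosome 8, 105566698 to 105637393). Npy went from 487 ± 23.7 to 1540 ± 660 CPM (1.66, SE 0.254, adjusted p = 0.0160; ENSMUSG00000029819, chromosome 6, 49822710 to 49829507). For all 4 genes the 3 Stat3KO libraries lay on 1 side of the 3 Ctrl libraries. Replicate 1 of Stat3KO held the highest level of each, 723 CPM of Agrp against 374 and 292, and 2295 CPM of Npy against 1255 and 1070. The calls on Agrp and Npy were lost when Ctrl bead-bound replicate 1, 2 or 3 was left out, with adjusted p = 0.0764, 0.0578 and 0.129 for Agrp and 0.0633, 0.0530 and 0.106 for Npy.

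**Figure D1:**
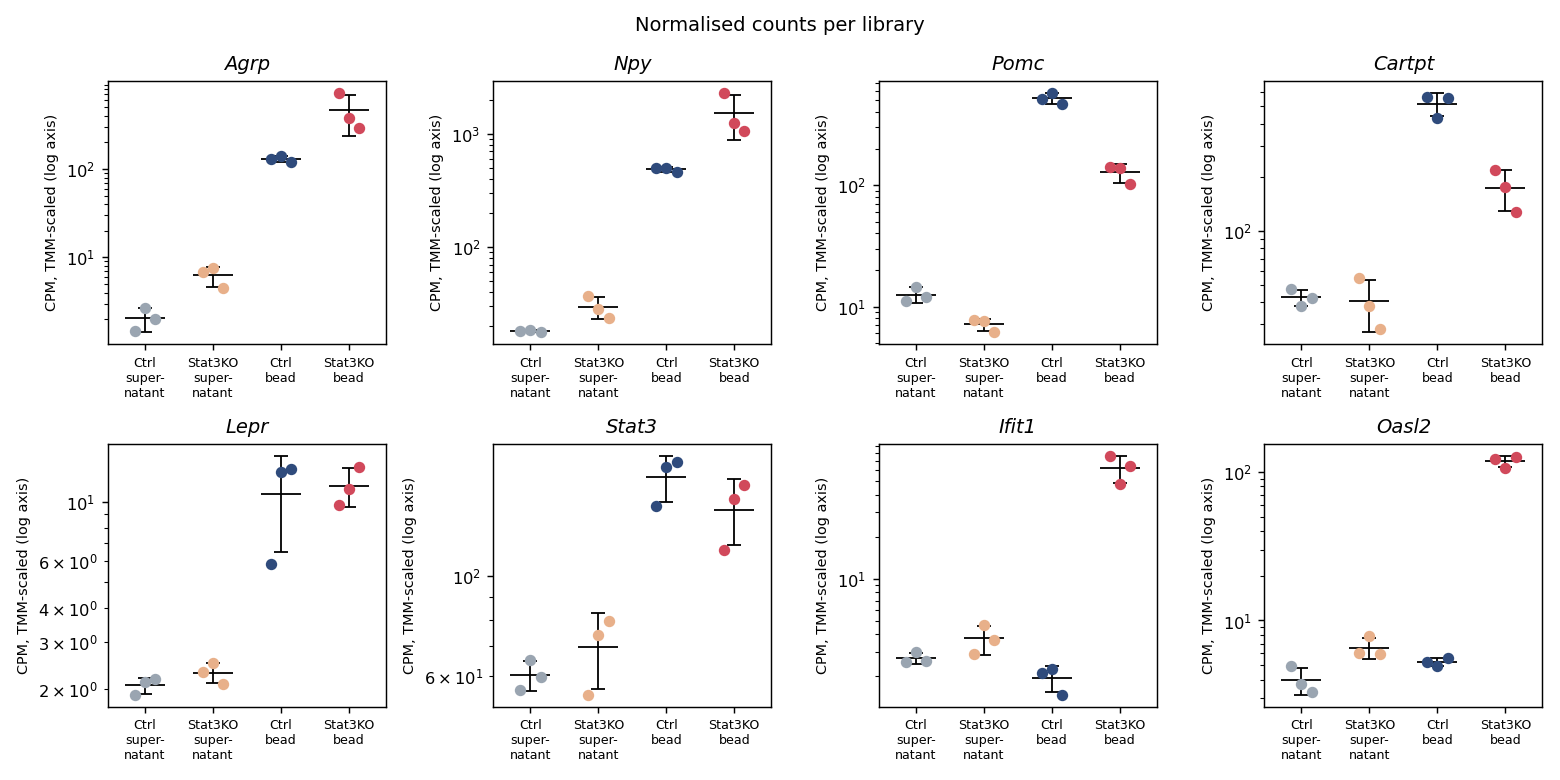
Levels in CPM (log axis) of 8 genes in the 4 groups: points are the 3 libraries of a group, dashes their means and bars their SD. Pomc and Cartpt lie lower and Agrp, Npy, Ifit1 and Oasl2 higher in Stat3KO than in Ctrl bead-bound RNA, while the levels of Stat3 and Lepr overlap between genotypes.

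Interferon-induced genes rose together in Stat3KO bead-bound RNA. Oasl2, of the antiviral oligoadenylate synthetase family, rose from 5.27 ± 0.317 to 118 ± 10.2 CPM (log2 fold change 4.48, SE 0.160, adjusted p = 7.98e-07). Bst2, which encodes tetherin, a protein that holds back budding virus, rose from 1.01 ± 0.207 to 46.6 ± 16.9 CPM (5.54, SE 0.311, adjusted p = 1.12e-05), and Ifit1, which binds viral RNA, from 1.95 ± 0.411 to 62.6 ± 13.7 CPM (5.01, SE 0.247, adjusted p = 6.99e-06). Irf9, a transcription factor of interferon signalling, rose by 1.10 (adjusted p = 0.00438; 0.0708 without Ctrl bead-bound replicate 2). Of the 38 tested members of the interferon list, 27 rose and 0 fell in edgeR, with 0 lower also in DESeq2, in limma-voom and at an unadjusted p under 0.05; 36 rose adjusted over the list alone. The list's median log2 fold change was 2.38 (adjusted p = 2.81e-91), and it passed with an estimated correlation (adjusted p = 0.0180) and with fry (adjusted p = 0.000777). The other largest rises were ranked among genes with a log2 of the mean CPM of at least 1 and no clone or model name. That mean covers both groups, so a rise from a Ctrl level near 0 could be ranked. These rises were the nucleic acid sensor Zbp1 (6.11) and the GTPases Ifi47 (5.52), Iigp1 (5.11), Gbp3 (4.77) and Irgm2 (4.52). With them were the protease inhibitor Serpina3f (5.05), the ubiquitin-like Isg15 (4.86), the MHC gene H2-Q6 (4.70) and Rtp4 (4.61). Lists written after these genes had been seen gave 16 of 19 interferon-induced GTPases higher (median 4.40). They gave 11 of 21 genes of MHC class I presentation higher (median 1.35); both include genes that prompted them, so their p are not given. Together the 3 lists held 45 of the 73 genes that rose.

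Of the 29 tested leptin and STAT3 targets 2 rose, Irf9 among them, and 1, Pomc, fell (4 higher and 4 lower adjusted over the list alone; list adjusted p = 0.347, with a median of 0.00154 and a mean of -0.0393). Socs3, the feedback inhibitor of leptin signalling, was at 5.71 CPM in Stat3KO and 6.01 CPM in Ctrl (log2 fold change -0.08), and the stress-induced transcription factor Atf3 at -0.18, each with adjusted p = 0.999. The protease inhibitor Serpina3n was at 81.6 ± 16.9 against 164 ± 28.2 CPM (-1.0, adjusted p = 0.0595; 0.000165 by DESeq2, 0.0256 without Stat3KO bead-bound replicate 1, 0.0486 with library totals and 0.0378 with all 12 libraries). In the neuropeptide list Agrp and Npy rose, Pomc and Cartpt fell and 42 members did not pass (2 higher and 3 lower adjusted over the list alone; median -0.161, adjusted p = 0.0217, and adjusted p = 0.776 with an estimated correlation). Without Stat3KO bead-bound replicate 2 or 3 or Ctrl replicate 1 that list had adjusted p = 0.269, 0.845 and 0.0637. Nts, the neurotensin gene, was at 52.1 ± 21.6 against 130 ± 41.1 CPM (-1.32, adjusted p = 0.169; 0.000447 by DESeq2 and 0.0144 without Stat3KO bead-bound replicate 1). Ghrh, of growth hormone-releasing hormone, was at 0.03 and Gal, of galanin, at -0.27, each with adjusted p = 0.999. The JAK-STAT pathway list of 33 members did not pass (adjusted p = 0.244, and 0.0258 without Stat3KO bead-bound replicate 1).

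Hormone and peptide receptors had a lower median in Stat3KO (-0.172 over 54 members, adjusted p = 3.24e-05; adjusted p = 0.776 with an estimated correlation). Ribosomal protein genes had a higher one (0.224 over 48 members, adjusted p = 3.24e-05; adjusted p = 0.776 with an estimated correlation, and 0.122 without Stat3KO bead-bound replicate 1). ER stress genes (median -0.189 over 29 members) had adjusted p = 0.0440, and adjusted p = 0.776 with an estimated correlation. It was 0.193 and 0.580 without Stat3KO bead-bound replicate 2 or 3 and 0.0889 and 0.168 without Ctrl replicate 2 or 3. In these 3 lists 0 members passed in edgeR and in limma-voom. At an unadjusted p under 0.05 there were 9, 1 and 3 such members, and by DESeq2 2 receptors were lower. The receptor genes Npy1r, for neuropeptide Y, at -0.82 and Sstr1, for somatostatin, at -0.67 were the 2 lower members adjusted over the list alone (adjusted p over all genes = 0.108 and 0.253). Further lists did not pass, namely peptide processing (adjusted p = 0.186), transmitter identity (0.130), hypothalamic transcription factors (0.206), immediate early genes (0.904), cholesterol synthesis (0.123), inflammation (0.292), oxidative phosphorylation (0.138), mitochondrially encoded genes (0.186), nuclear noncoding RNAs (0.317) and sex-linked genes (0.244). Leaving out 1 library brought all of these but the immediate early genes past the test in at least 1 fit, the lowest being oxidative phosphorylation without Stat3KO bead-bound replicate 2 (adjusted p = 0.000394).

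Of the cell type markers, 2 lists passed the test between genotypes in bead-bound RNA. Oligodendrocyte markers had a median of -0.186 over 15 members (adjusted p = 0.0496; adjusted p = 0.776 with an estimated correlation), with the galactolipid enzyme gene Ugt8a lower adjusted over the list alone (-0.76). The call was lost without Stat3KO bead-bound replicate 2 or 3 or Ctrl replicate 3 (adjusted p = 0.114, 0.646 and 0.0539), and the direction turned without Ctrl replicate 1 (0.920). Markers of striatum and cortex had a median of -0.385 over 11 members (adjusted p = 0.00619; adjusted p = 0.776 with an estimated correlation and 0.249 without Stat3KO bead-bound replicate 2). Neurons (adjusted p = 0.292), astrocytes (0.182), oligodendrocyte precursors (0.224), microglia (0.157), endothelium (0.244), mural cells (0.254), ependyma and tanycytes (0.688), fibroblasts (0.839), choroid plexus (0.277), blood (0.171) and thalamus (0.773) did not pass, and pituitary had too few tested members. Leaving out 1 library brought astrocytes, precursors, microglia, endothelium, mural cells and blood past the test in at least 1 fit, the lowest being microglia without Stat3KO bead-bound replicate 1 (adjusted p = 0.000395). The median and the test differed in sign for endothelium (0.0268, tested as lower), and the median (0.0494) and mean (-0.00195) for thalamus. In all marker lists 0 members passed in edgeR, DESeq2 and limma-voom, and each list had 0 or 1 members at an unadjusted p under 0.05.

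Libraries differed within groups too. The share of mitochondrially encoded transcripts was 0.134% in Ctrl bead-bound replicate 1 and 0.0149% to 0.0311% in the other bead-bound libraries. Endothelial markers in bead-bound RNA had mean log2 CPM of 1.47, 4.15 and 3.63 in Stat3KO and 2.99, 3.23 and 3.98 in Ctrl replicates 1, 2 and 3. In Stat3KO supernatant they had 1.74, 1.97 and 1.60, so in replicate 1 they were not higher on the beads. Replicate 1 stood apart in every group, with a chi-square per gene against replicates 2 and 3 of 92.9 and 93.8 in Stat3KO bead-bound RNA (19.3 between these) and of 59.4 and 89.2 in Ctrl bead-bound RNA (15 between these).

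Of 17354 genes tested in bead-bound RNA, 73 were higher and 5 lower in Stat3KO by edgeR. Besides Pomc and Cartpt these 5 were A830036E02Rik (-3.72, adjusted p = 0.00591), the keratin gene Krt12 (-2.90, adjusted p = 0.0204) and Gm10704 (-3.10, adjusted p = 0.0408), which were chosen after their values were seen. At an unadjusted p under 0.05 there were 713 genes, against 868 by chance alone, and in 9.38% of tested genes the groups did not overlap, against 10% by chance. DESeq2 called 108 higher and 16 lower. With replicates 2 and 3 alone, a choice made after seeing the data, 273 were higher and 894 lower, and these included all 78 genes.

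The comparison of the supernatants asks whether RNA left after the pull-down, mostly from cells without Cre, also differed by genotype. It can still hold RNA of LepRb cells, so a change there need not lie in other cells. A830036E02Rik, a gene known by a clone name, fell from 18.0 to 0.484 CPM (log2 fold change -5.17, SE 0.271, adjusted p = 6.17e-06), and Krt12, which encodes a keratin and overlaps it on chromosome 11, from 2.80 to 0.317 CPM (-3.13, SE 0.313, adjusted p = 0.00399). These were the only genes of 18547 that passed in edgeR, and they are named after their values were seen. A830036E02Rik lies at 99416956 to 99425497 and Krt12 at 99415666 to 99422259, close to Stat3. Agrp was at 6.27 ± 1.61 against 2.04 ± 0.606 CPM (1.60, adjusted p = 0.0895; 2.63e-06 by DESeq2 and 0.0354 without Stat3KO supernatant replicate 3). Npy was at 29.8 ± 6.54 against 18.3 ± 0.435 CPM (0.70, adjusted p = 0.329; 0.00872 by DESeq2). Pomc was at 7.12 ± 0.830 against 12.5 ± 1.84 CPM (-0.82, adjusted p = 0.197; 0.00242 by DESeq2). Cartpt was at -0.08 (adjusted p = 0.964), Lepr at 0.15 (0.930) and Oasl2 at 0.73 (0.488). The vasopressin gene Avp was at 0.91 (adjusted p = 0.176; 0.0354 without Stat3KO supernatant replicate 3) and the astrocyte water channel gene Aqp4 at -0.83 (0.0895).

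**Figure D2:**
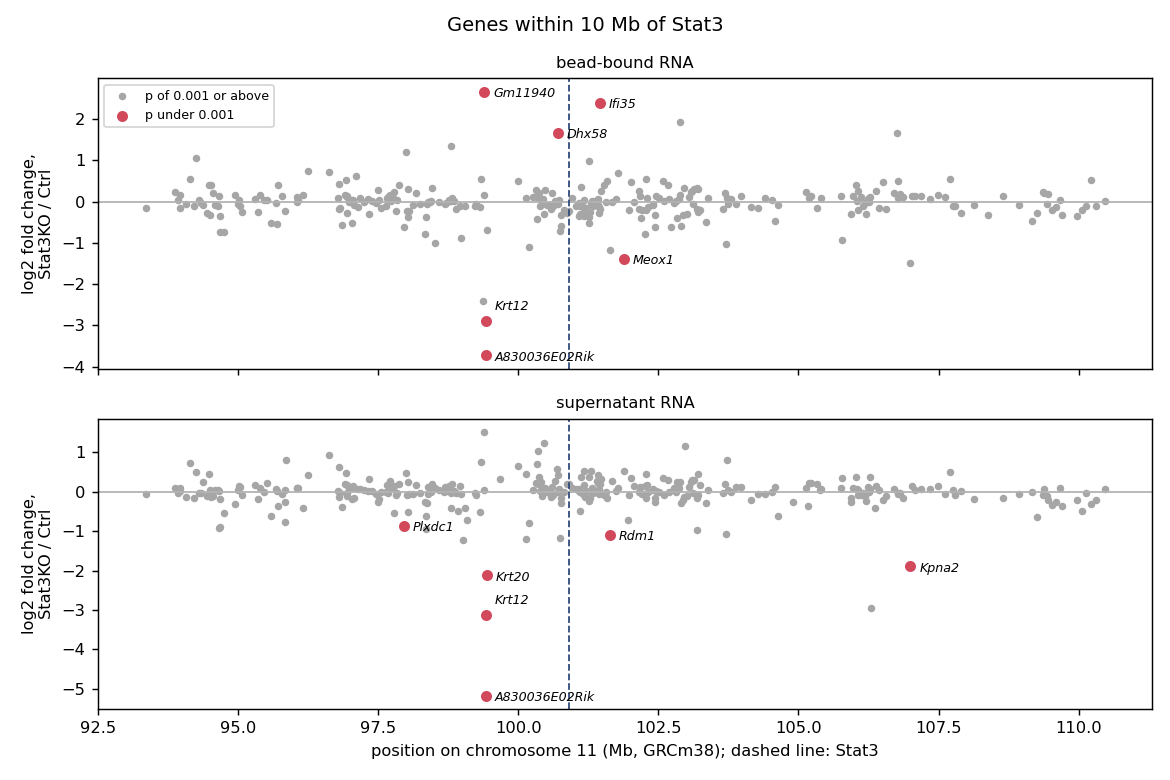
Log2 fold change of Stat3KO over Ctrl in bead-bound and supernatant RNA (2 panels) against position on chromosome 11 in Mb (GRCm38) within 10 Mb of Stat3, whose place is the dashed line; each point is a tested gene, red where its unadjusted p was under 0.001. A830036E02Rik and Krt12 lie far below 0 in both panels, at -3.72 and -2.90 in bead-bound RNA and -5.17 and -3.13 in supernatant.

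Markers of glia had lower medians in Stat3KO supernatant. Oligodendrocyte markers had a median of -0.327 over 15 members (adjusted p = 8.72e-06), with the galactolipid enzyme gene Ugt8a at -0.80 and the myelin gene Opalin at -0.51. Microglial markers were at -0.311 over 14 members (adjusted p = 4.25e-05), with the chemokine receptor gene Cx3cr1 at -0.63. Oligodendrocyte precursor markers were at -0.236 over 9 members (adjusted p = 0.000142), with Gpr17 at -0.77. Astrocyte markers were at -0.295 over 15 members (adjusted p = 0.00203), with the gap junction gene Gja1 at -0.58. Each of these 4 had adjusted p = 0.535 with an estimated correlation. Adjusted over the list alone 7, 2, 1 and 2 of these markers were lower. Markers of striatum and cortex were at -0.550 over 11 members (adjusted p = 0.000142; adjusted p = 0.583 with an estimated correlation). Among them were Rgs9, of a striatal regulator of G protein signalling, at -0.65 and the dopamine receptor gene Drd2 at -0.54. Their mean log2 CPM was 4.04, 2.77 and 3.25 in Stat3KO and 4.00, 4.04 and 4.04 in Ctrl supernatant replicates 1, 2 and 3, so Stat3KO replicate 1 lay at the Ctrl level. Microglial markers in Stat3KO replicate 1 (3.11) also lay within the Ctrl libraries (3.08 to 3.21). Blood transcripts were at 0.228 (adjusted p = 0.0211; adjusted p = 0.743 with an estimated correlation). Without Stat3KO supernatant replicate 1 Opalin, Cx3cr1 and Drd2 passed the gene test (adjusted p = 0.0494, 0.0389 and 0.0394).

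The interferon list had a median of 0.159 over 38 members in supernatant (adjusted p = 0.000130; adjusted p = 0.535 with an estimated correlation), with 4 higher and 1 lower adjusted over the list alone. Ribosomal protein genes (median 0.165, adjusted p = 0.000142), oxidative phosphorylation genes (0.0989, adjusted p = 0.000130) and hormone and peptide receptors (-0.158, adjusted p = 0.00415) had adjusted p = 0.743 with an estimated correlation. Hypothalamic transcription factors (0.103, adjusted p = 0.0385) had adjusted p = 0.535 with an estimated correlation. The other lists did not pass: leptin and STAT3 targets (adjusted p = 0.847), JAK-STAT (0.426), neuropeptides (0.802), peptide processing (0.581), transmitter identity (0.65), immediate early genes (0.389), ER stress (0.324), cholesterol synthesis (0.426), inflammation (0.485), mitochondrially encoded (0.565), nuclear noncoding (0.324) and sex-linked (0.426). Nor did the markers of neurons (0.258), endothelium (0.655), mural cells (0.590), ependyma (0.455), fibroblasts (0.0759), pituitary (0.330), choroid plexus (0.0753) and thalamus (0.103). Median and mean differed in sign for leptin targets (0.0329 and -0.0123), neuropeptides (-0.0266 and 0.0497) and endothelium (median 0.0283, tested as lower). In edgeR and limma-voom 0 members of any list passed. By DESeq2 3 neuropeptides and 1 immediate early gene were higher and 1 member each of 5 lists was lower. Each list had between 0 and 9 members at an unadjusted p under 0.05.

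By edgeR 0 genes were higher and 2 lower in supernatant; 1149 had an unadjusted p under 0.05 against 927 by chance, and in 12.7% the groups did not overlap, against 10% by chance. DESeq2 called 14 higher and 29 lower, and limma-voom 0 higher and 2 lower. The count was 43 without Stat3KO supernatant replicate 1, 7 without replicate 3, 4 without Ctrl supernatant replicate 1 and 988 with replicates 2 and 3 alone, a choice made after seeing the data. Replicate 1 stood apart with a chi-square per gene of 48.3 and 51.0 in Stat3KO (14.8 between the others) and of 31.2 and 36.2 in Ctrl (6.78).

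The difference of the bead to supernatant ratio between genotypes asks whether the genotypes differed more in bead-bound than in supernatant RNA. A transcript enriched on the beads, such as Agrp (by 5.96 in Ctrl), may reach the supernatant from LepRb cells too. For such genes a like change in both fractions does not place it outside these cells. Interferon-induced genes had a higher ratio in Stat3KO: Isg15 by 4.83 (SE 0.465, adjusted p = 0.000110), Ifit1 by 4.54 (SE 0.316, adjusted p = 6.3e-06) and Oasl2 by 3.74 (SE 0.228, adjusted p = 2.04e-06) on the log2 scale. Of the 39 tested members of the list 17 were higher and 0 lower in edgeR, with 0 lower also in DESeq2, in limma-voom and at an unadjusted p under 0.05 (34 higher adjusted over the list alone; median 1.85, adjusted p = 3.89e-106, and adjusted p = 0.000187 with an estimated correlation). Of the genes called between genotypes in bead-bound RNA 67 were also tested in supernatant, where 61 had the same sign and 24 of these an unadjusted p under 0.05. The 62 of these 67 genes that rose in bead-bound RNA had a median log2 fold change of 2.55 there and of 0.335 in supernatant. Pomc had a lower ratio in Stat3KO (-1.22, SE 0.219, adjusted p = 0.0352; 0.0616 to 0.141 when any of 8 libraries was left out, and 0.0709 by limma-voom).

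**Figure D3:**
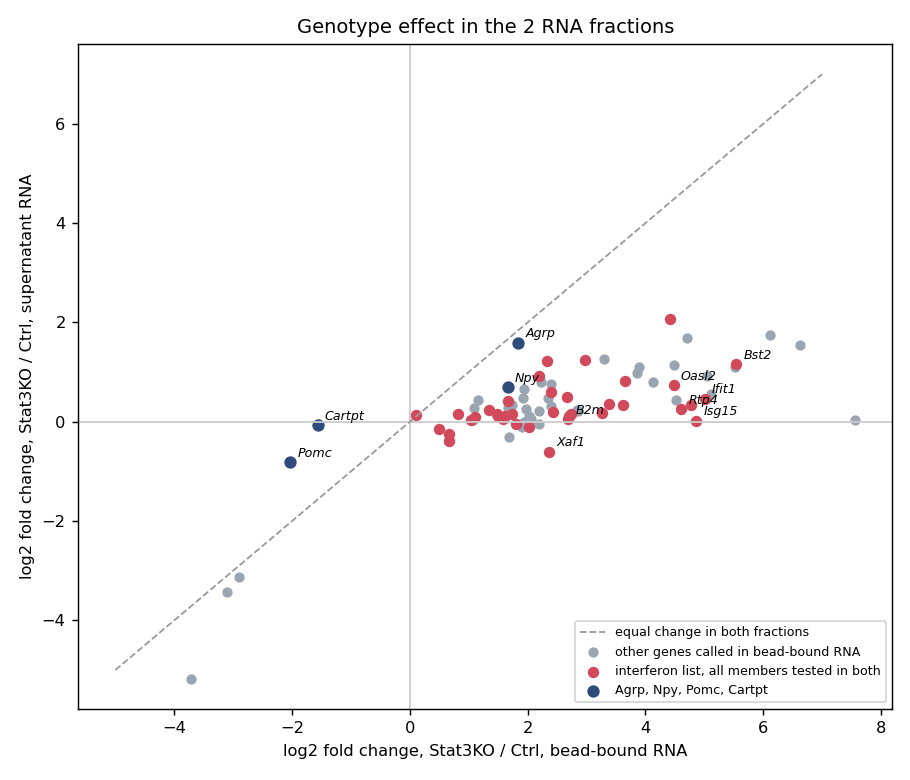
Log2 fold change of Stat3KO over Ctrl in bead-bound RNA (x) and in supernatant (y) for genes tested in both. Shown are the 67 called bead-bound genes and the interferon list members that were not called. Red marks all interferon list members, called or not, and blue Agrp, Npy, Pomc and Cartpt. Grey marks the other called genes, and the dashed line equal change. Most red points lie far to the right and near 0 in supernatant, while Agrp has 1.84 in bead-bound RNA and 1.60 in supernatant.

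The ratio of Agrp did not differ by the test (0.24, adjusted p = 1). Cartpt was at -1.49 (adjusted p = 0.117; 1.66e-05 with pool as a block, 0.00321 by DESeq2, 0.0447 without Stat3KO bead-bound replicate 1 and 0.0388 without Stat3KO supernatant replicate 3). Npy was at 0.95 (adjusted p = 1; 0.0105 with the block), Nts at -0.99 (adjusted p = 1; 0.0272 with the block) and Serpina3n at -1.13 (adjusted p = 0.438; 0.00358 with the block). Neuropeptides had a median of -0.225 over 47 members (0 higher, 1 lower, and 2 lower adjusted over the list alone; adjusted p = 0.00567, and adjusted p = 0.871 with an estimated correlation). Hypothalamic transcription factors were at -0.139 over 38 (adjusted p = 0.000956, and adjusted p = 0.162 with an estimated correlation). Choroid plexus markers were at 0.440 over 8 (adjusted p = 0.0192, and adjusted p = 0.871 with an estimated correlation). By edgeR, DESeq2 and limma-voom 0 members of the last 2 lists and 0 higher neuropeptides passed; 5 transcription factors and 1 higher and 4 lower neuropeptides, and 0 choroid plexus markers, had an unadjusted p under 0.05. Peptide processing genes had adjusted p = 0.0960 (0.00852 with the block) and leptin targets 0.707 (3 higher and 3 lower of 30 adjusted over the list alone), and the remaining lists 0.0744 to 0.804. Median and mean differed in sign for leptin targets, JAK-STAT, inflammation and mural genes, and the test differed in sign from both for endothelium and pituitary. In all 37 genes were higher and 2 lower of 19122 tested, the other lower one being Meox1, a homeobox gene near Stat3 (-1.91, adjusted p = 0.0330; 0.0556 to 0.134 without any of 10 libraries and 0.0501 with the block). The block gave 59 genes, of which 36 were shared with these, and the count was 24 without Ctrl supernatant replicate 3.

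The comparison of bead-bound with supernatant RNA asks which transcripts the pull-down of LepRb cells enriches. In Ctrl, Agrp was higher in bead-bound RNA by 5.96 on the log2 scale (SE 0.206, adjusted p = 5.19e-06), Pomc by 5.38 (SE 0.161, adjusted p = 2.38e-06), Npy by 4.74 (SE 0.110, adjusted p = 5.64e-07) and Prlh, of the prolactin-releasing peptide, by 5.28. In Stat3KO these were 6.18 (SE 0.389, adjusted p = 2.42e-05), 4.15 (SE 0.181, adjusted p = 1e-05), 5.68 (SE 0.332, adjusted p = 1.92e-05) and 5.08. Lepr was higher by 2.37 in Ctrl (SE 0.303, adjusted p = 0.000854) and by 2.30 in Stat3KO (SE 0.190, adjusted p = 8.71e-05), and Stat3 by 1.46 and 1.01. Gfp_L10a was higher by 3.60 and 3.38, Cartpt by 3.62 and 2.11, Ghrh by 3.56 and 3.54, Nts by 2.45 and 1.45, and Gal by 1.90 and 1.49. Socs3 was higher by 1.47 and 1.15 (in Stat3KO adjusted p = 0.0529 without Stat3KO supernatant replicate 3). Serpina3n was higher by 3.81 and 2.67.

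Neuropeptide genes were enriched on the beads, with 28 of 47 higher and 3 lower in Ctrl and 18 and 6 in Stat3KO (28 and 5, and 19 and 7, adjusted over the list alone). Their medians were 0.801 and 0.538 (adjusted p = 1.49e-06 and 0.000256). Of the leptin and STAT3 targets 13 of 28 were higher and 1 lower in Ctrl and 14 and 1 in Stat3KO, the same adjusted over the list alone, with medians of 0.682 and 0.914 (adjusted p = 0.000560 and 4.73e-06). Of 38 hypothalamic transcription factors 22 and 21 were higher and 10 and 8 lower (22 and 21, and 10 and 9, adjusted over the list alone; medians 0.840 and 0.675, adjusted p = 0.000303 and 0.000151). Examples are Nr5a1, a factor of the ventromedial nucleus, by 3.42 and 2.66 and Tbx3, a factor of arcuate neurons, by 3.41 and 2.79. Of 26 peptide processing genes 17 and 13 were higher, 18 and 14 adjusted over the list alone, and 1 was lower in Stat3KO (medians 0.768 and 0.553, adjusted p = 6.73e-06 and 2.12e-05). Of 54 hormone and peptide receptors 23 and 18 were higher and 5 and 4 lower (25 and 21, and 5 and 6, adjusted over the list alone; medians 0.450 and 0.383, adjusted p = 0.000165 and 9.17e-05). Among them were Mc3r, a melanocortin receptor gene, by 2.49 and 2.27 and Calcr, of the calcitonin receptor, by 2.31 and 2.20. With an estimated correlation the adjusted p of these 5 lists were 0.237 to 0.409 in Ctrl and 0.356 to 0.682 in Stat3KO. ER stress genes were also higher, 13 and 8 of 29, with 2 and 3 lower (13 and 10 higher adjusted over the list alone), with medians of 0.461 and 0.332 (adjusted p = 0.00752 and 0.0298). Of 62 oxidative phosphorylation genes 45 and 27 were higher, 52 and 34 adjusted over the list alone, and 1 was lower in each (medians 0.485 and 0.432, adjusted p = 7.72e-10 and 7.08e-08). Of 48 ribosomal protein genes 36 and 37 were higher, 39 and 38 adjusted over the list alone, and 1 was lower in each (medians 0.815 and 0.884, adjusted p = 9.7e-11 and 7.3e-13). These 3 lists had adjusted p = 0.306 to 0.409 in Ctrl and 0.482 to 0.682 in Stat3KO with an estimated correlation. The interferon list passed in Stat3KO, with 33 of 39 higher (35 adjusted over the list alone; median 2.24, adjusted p = 9.53e-20; adjusted p = 0.356 with an estimated correlation), and not in Ctrl, with 10 higher and 6 lower of 36 (adjusted p = 0.421). Th and Slc6a3, dopamine synthesis and transport genes, were higher by 2.85 and 3.17 in Ctrl and by 2.58 and 2.72 in Stat3KO. The transmitter list did not pass (adjusted p = 0.483 and 0.780; its medians -0.0788 and -0.0692 differ in sign from the test).

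Glial markers were depleted. All 15 oligodendrocyte markers were lower in each genotype (medians -1.60 and -1.43, adjusted p = 8.31e-07 and 1.12e-08). Of 15 astrocyte markers 12 and 15 were lower (-1.13 and -1.01, adjusted p = 4.4e-05 and 1.42e-06), and of 14 microglial markers 12 and 11 (-1.55 and -1.46, adjusted p = 7.6e-05 and 5.07e-05). Of 9 precursor markers 6 were lower in each (-1.34 and -1.34, adjusted p = 0.00700 and 0.000865). All 7 tested mitochondrially encoded genes were lower in each (-3.96 and -5.35, adjusted p = 0.000643 and 5.34e-08). Of 14 nuclear noncoding RNAs 10 and 8 were lower and 3 and 2 higher (11 and 10 lower adjusted over the list alone; medians -1.88 and -1.50, adjusted p = 0.00416 and 0.00342). So were blood (-0.953 and -1.11, adjusted p = 0.0163 and 0.00259) and thalamus markers (-0.707 and -0.885, adjusted p = 0.0456 and 0.0159). Adjusted over the list alone 13 astrocyte and 13 microglial markers in Ctrl and 12 microglial markers in Stat3KO were lower, 7 precursor markers in each, and 13 and 12 endothelial markers were higher. With an estimated correlation these depleted lists had adjusted p = 0.409 to 0.434 in Ctrl and 0.356 to 0.544 in Stat3KO. Endothelial markers were higher, 12 and 9 of 13 (1.73 and 1.83). In Stat3KO replicate 1 they were not, at a mean log2 CPM of 1.47 on the beads and 1.74 in supernatant. Their adjusted p were 5.32e-06 and 0.00259, and adjusted p = 0.409 and 0.637 with an estimated correlation. Flt1, of a receptor of vascular growth factor, was at 2.61 and 2.72 (in Stat3KO adjusted p = 0.0537, 0.0579 and 0.0593 without supernatant replicate 1, 2 or 3). Fibroblast markers passed in Ctrl (-0.682, adjusted p = 0.0157, and adjusted p = 0.453 with an estimated correlation) and not in Stat3KO (0.0619). The strongest depletion was of mitochondrial transcripts, mt-Nd2 by -4.07 and -5.58 and mt-Cytb by -3.99 and -5.65; without Ctrl bead-bound replicate 1 mt-Cytb was at -6.25 in Ctrl.

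**Figure D4:**
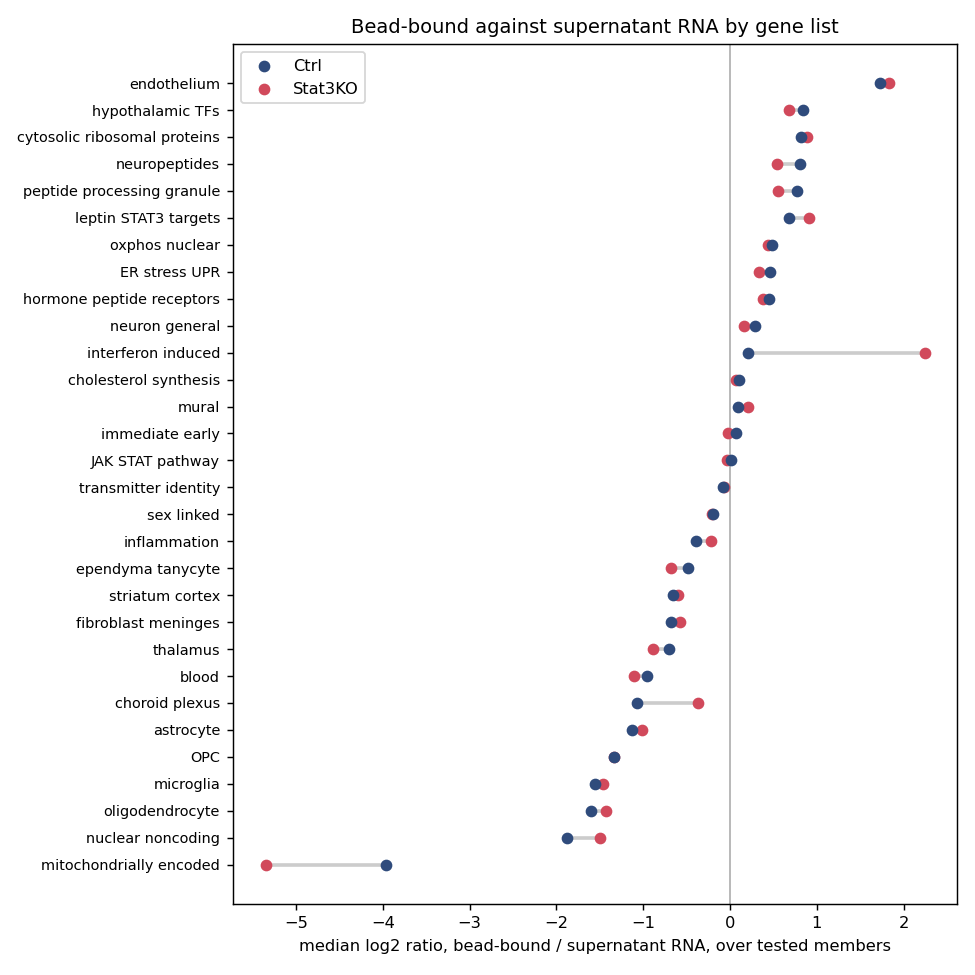
Median log2 ratio of bead-bound to supernatant RNA for each gene list in Ctrl (blue) and Stat3KO (red). Mitochondrially encoded genes lie lowest, at -3.96 and -5.35, and the interferon list lies at 0.205 in Ctrl and 2.24 in Stat3KO.

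The lists that did not pass in Ctrl and Stat3KO were JAK-STAT (adjusted p = 0.483 and 0.365), immediate early genes (0.483 and 0.795), cholesterol synthesis (0.144 and 0.363), inflammation (0.254 and 0.197) and sex-linked genes (0.622 and 0.795). Nor did markers of neurons (0.0989 and 0.365), mural cells (0.483 and 0.843), ependyma (0.0935 and 0.0972), choroid plexus (0.144 and 0.859) and striatum with cortex (0.115 and 0.780). Pituitary had 0.483 in Ctrl and too few members in Stat3KO. In Stat3KO the median and mean differed in sign for JAK-STAT, and the test from both for immediate early and mural genes. The median of all genes was -0.157 in Ctrl and -0.124 in Stat3KO with library totals, and -0.00676 and -0.0216 with TMM. With library totals the medians of JAK-STAT, immediate early, cholesterol and mural genes in Ctrl and of cholesterol genes in Stat3KO turned below 0. Of 18036 genes 3735 were higher and 3829 lower on beads in Ctrl, and of 18107 genes 2669 and 3135 in Stat3KO. Among the 17603 genes tested in both 2337 were higher in both genotypes, against 557.5 for independent lists, and 2537 lower in both, against 647.5. With pool as a block Ctrl gave 10544 genes and Stat3KO 8999. Stat3KO gave 2879 and 3428 without supernatant replicate 2 or 3, and Ctrl 4866 without supernatant replicate 2. Library totals in place of TMM gave 2387 higher and 4906 lower in Ctrl, and 1842 and 3716 in Stat3KO.

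Averaged over both genotypes, Agrp (6.08), Npy (5.21), Prlh (5.18), Pomc (4.77), the homeobox gene Gsx1 (3.79), the T-box gene Tbx19 (3.68), the keratin gene Krt90 (3.57) and Ghrh (3.55) had the highest log2 ratios of bead-bound to supernatant RNA among the named genes. Of 19122 genes 5012 were higher and 5488 lower, and 2217 and 3964 by at least 1.5 fold. Library totals in place of TMM gave 3630 higher and 6722 lower, and pool as a block gave 12506 genes in all. Of the lists 19 passed, and 0 with an estimated correlation but 24 with fry. Of the leptin and STAT3 targets 17 of 30 were higher (18 adjusted over the list alone; median 0.828, adjusted p = 3.69e-05, and adjusted p = 0.132 with an estimated correlation). Of the interferon list 26 of 39 were higher, 26 also adjusted over the list alone (1.48, adjusted p = 3.4e-09, and adjusted p = 0.185 with an estimated correlation).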

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

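Of the tests here, the comparison of the interferon list between fractions, its distance from Stat3, and all tests of genes near Stat3 were chosen only after the results were seen.

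The effect of genotype differed between bead-bound and supernatant RNA in 39 genes and in 4 gene lists, by a test of the difference itself. On the log2 scale the difference was 4.834 for Isg15, 4.549 for Iigp1, 4.54 for Ifit1, 4.415 for Gbp3, 4.399 for Ifi47, 4.355 for Bst2, 4.347 for Rtp4, 4.068 for Irgm2, 3.741 for Oasl2, 3.325 for Gbp6, 3.295 for H2-Q7 and 3.28 for Usp18, and it was -1.22 for Pomc and -1.908 for Meox1. The lists were the interferon-induced genes (adjusted p = 3.89e-106), neuropeptides (0.00567), hypothalamic transcription factors (0.000956) and choroid plexus markers (0.0192). With an estimated correlation these had adjusted p = 0.000187, 0.871, 0.162 and 0.871. Without Ctrl supernatant replicate 3 the adjusted p of Ifi47 and Gbp6 became 0.134 and 0.0702, and the count of genes 24. H2-Q7 lost its call without any of 9 libraries (adjusted p = 0.0561 to 0.317), Pomc without any of 8 (0.0616 to 0.141) and Meox1 without any of 10 (0.0556 to 0.134).

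The rise of interferon-induced genes in Stat3KO bead-bound RNA was much smaller in supernatant. A response of all hypothalamic cells alike needs a median difference between fractions near 0, and over 39 genes it was 1.852 with 38 above 0, which argues against it. Microglia or leukocytes in the pull-down would bring their own markers, against a median rise of 2.74 of the called interferon genes. But microglial markers had a median of -0.2248 (SE of the list mean over libraries 0.473), with P2ry12 at -0.18 and Csf1r at -0.22. Leukocyte markers had a median of -0.503 (SE over genes 0.36, with 5 of 19 members tested). Alleles carried along with the floxed Stat3 gene, if they act on nearby genes, would place called list members near it. Of the 27, 0% lay within 20 Mb. Of all 78 called genes 3 did, among them Ifi35, which is interferon-induced but not on the list. The list member Dhx58, also near Stat3, rose by 1.665 without passing (adjusted p = 0.0774). Position cannot speak to a linked allele that acts on distant genes. A candidate explanation that stays open is a response of LepRb cells to the loss of STAT3.

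Some genes near Stat3 on chromosome 11 differed between the genotypes in supernatant or in bead-bound RNA, but few did in both. In supernatant, where this was first seen, 6 of 328 genes within 10 Mb had an unadjusted p under 0.001, against 36 of 18219 others. In bead-bound RNA of the same pools these were 6 of 311 against 97 of 17043, and only the overlapping Krt12 and A830036E02Rik were among the 6 in both. With the genes picked in supernatant and interferon-induced genes left out, 2 of 303 remained against 68 of 17006 (odds ratio 1.66, Fisher exact p = 0.3474). Alleles of another strain linked to the floxed gene cannot be told apart from other causes, since so few genes remain and no strain variants were analysed here.

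The 6 genes near Stat3 picked in supernatant were all lower there, by 45% to 97.2%. Suppose STAT3 was lost in LepRb cells alone and other cells did not respond. Then that share of the supernatant RNA of the 6 genes comes from LepRb cells. It would be enriched on the beads about as Lepr is (2.37 in Ctrl, the least of Lepr, Cre and Gfp_L10a). The Ctrl log2 ratios of all 6 lay below the ratio this needs, by a median of -2.27 (SE over genes 0.743). This cannot decide the question, since it takes each transcript to bind ribosomes as Lepr does and other cells not to respond. Nuclear noncoding RNAs were depleted on the beads in Ctrl (median -1.88). The 6 were also picked by the supernatant falls that set the needed ratio. Krt12 and A830036E02Rik overlap, so the 6 are not independent. For the 4 genes picked in bead-bound RNA alone the same explanation cannot be told apart: 2 are interferon-induced, and the other 2, Meox1 (of opposite sign in supernatant) and Gm11940, with a median absolute ratio of supernatant to bead-bound change of 0.4731, are too few.

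The groups were also split in every other way. The split by genotype gave 78 genes in bead-bound RNA, and it was 1 of 10 splits with as many, the highest other giving 0. In supernatant 2 of 10 splits gave 2 genes or more, with the highest other at 2. Between fractions the real split was 1 of 10 in Ctrl (7564 genes, highest other 0) and 1 of 10 in Stat3KO (5804 genes, highest other 0), where the pools pair the samples: the 4 splits that part all 3 pairs, the real one among them, gave at most 0 otherwise, and the 6 that part 1 pair gave at most 0. For the difference of ratios it was 1 of 10 splits of the pools (39 genes, highest other 0). These splits are too few for a share under 0.05. For the ratio averaged over both genotypes the real split was 1 of 100 drawn from 200 (10500 genes, highest other 44). It was also 1 of the 32 splits that part the 2 libraries of all 6 pools (highest other 44), so a random grouping of the libraries can be excluded.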

How the results depend on the processing

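The fits on replicates 2 and 3 alone were chosen only after the results were seen. Genes between the genotypes in bead-bound RNA came to 124 with DESeq2 (77 of the 78 kept), 183 with no filter on low counts, 41 with the stricter filter and 1167 with replicates 2 and 3 alone (all 78 kept). All other settings gave 58 to 101. In supernatant, where the test called 2, the count was 10 at an adjusted p under 0.1, 43 with DESeq2, 203 with no filter, 1 with the stricter filter, 4 with the replicate number as a block, 988 with replicates 2 and 3 alone, and 2 to 43 when 1 library was left out. Between fractions in Ctrl it was 2600 at 2 fold or more, 4979 with the stricter filter and 4866 to 8813 when 1 library was left out. With pool as a block Ctrl had 10544. In Stat3KO the same settings gave 2125, 3769 and 2879 to 6410, and 8999 with pool as a block. The difference of ratios gave 63 with DESeq2, 97 with no filter, 59 with the block and 24 to 35 when 1 library was left out. The averaged ratio gave 6181 at 1.5 fold or more and 6561 with the stricter filter, and 9546 to 10757 when 1 library was left out. The filters and the fold minimum lower the counts by testing or admitting fewer genes; for the other settings the cause was not tested.

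With an estimated correlation 1, 0, 0, 0, 1 and 0 lists passed in bead-bound RNA, in supernatant, between fractions in Ctrl and in Stat3KO, in the difference of ratios and in the averaged ratio, in place of 7, 11, 18, 18, 4 and 19. With fry these were 1, 0, 24, 14, 1 and 24. In bead-bound RNA 6 to 15 lists passed when 1 library was left out. The oligodendrocyte list there had adjusted p = 0.000118 to 0.92, and it turned direction without Ctrl bead-bound replicate 1 (0.92); the cause was not tested. Between genotypes the block was the replicate number, which does not pair their pools. In supernatant it ended the call on hypothalamic transcription factors (adjusted p = 0.0506). It gave calls there on pituitary (0.0407), choroid plexus (0.0394) and thalamus markers (0.0394). In bead-bound RNA it ended the call on ER stress (0.135) and gave a call on microglia (0.0236).

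For single named genes, 4913 of 5094 tests with 1 library left out stayed on the same side of the threshold, whether called or not, 170 lost a call and 11 gained one. For the block these were 625, 1 and 4 of 630, and for replicates 2 and 3 alone 563, 6 and 61 of 630. For the other settings they were 3949, 34 and 47 of 4030. These counts pool all comparisons, and many of the genes were picked for large changes in the same data. Over all settings, genes called in the difference of ratios lost the call in 39 of 297 tests. Those called between genotypes in bead-bound RNA lost it in 7 of 269. Lists, called or not, stayed on the same side in 138 of 180 tests with 1 library left out (12 lost a call, 29 gained one, 1 reversed), in 176 of 184 with the block (3 lost, 5 gained) and in 258 of 368 in the other settings (99 lost, 11 gained). With 31.3% of 2-fold changes found in simulated data, the difference of ratios leaves most smaller changes undetected.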

Other observations

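The sharing of Ctrl bead-bound replicate 1 with supernatant RNA was tested only after the result was seen, and the list of other glucocorticoid-responsive genes was written after Sgk1, Fkbp5, Cdkn1a and Plin4 had been seen, but before its own values were.

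Some transcripts that respond to glucocorticoids, the adrenal stress hormones, lay higher in Stat3KO supernatant, though those named here did not pass the gene test. Sgk1, a kinase gene that glucocorticoids induce, was at 182, 213 and 146 CPM in Stat3KO and at 98.4, 90.4 and 70.4 CPM in Ctrl replicates 1, 2 and 3 (log2 fold change 1.06, adjusted p = 0.0895). Fkbp5, which encodes a chaperone of the glucocorticoid receptor, was at 67.1, 79.4 and 66.1 against 43.8, 44.8 and 46.6 CPM (0.65, adjusted p = 0.105). Cdkn1a, of a cell cycle inhibitor, was at 1.16 (adjusted p = 0.197) and Plin4, of a lipid droplet protein, at 1.36 (adjusted p = 0.211). Tsc22d3, also induced by glucocorticoids, overlapped between genotypes, at 157, 178 and 159 CPM in Stat3KO and 175, 145 and 142 CPM in Ctrl supernatant. A wider rise of such genes was tested on 27 others: their median was 0.269, 23 lay above 0, and camera gave p = 1.323e-07 (p = 0.0280 with an estimated correlation), which is consistent with it. In edgeR 0 of the 27 passed, and 9 had an unadjusted p under 0.05. The median was 0.227 to 0.347 when 1 library was left out. The mean log2 CPM of the list in replicates 1, 2 and 3 was 3.91, 4.06 and 3.90 in Stat3KO and 3.84, 3.61 and 3.60 in Ctrl, so Ctrl replicate 1 lay near the Stat3KO level. In bead-bound RNA the median was 0.245 over 28 genes (p = 2.8e-05; p = 0.179 with an estimated correlation), but Ctrl replicate 1 (3.69) lay above Stat3KO replicates 1 and 3 (3.59 and 3.43). The difference between fractions had a median of -0.0571 over 28 genes (p = 0.894; p = 0.955 with an estimated correlation). Whether hormone levels or handling differed between the genotypes is not given in the sources used here.

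Among the genes tested between fractions in each genotype, 8 were lower on the beads in Ctrl and higher in Stat3KO. They include Isg15 (-1.15 and 3.66), Xaf1 (-1.37 and 1.59), Ifit3 (-0.93 and 1.63), Ifit2 (-0.62 and 0.87), the transcription factor gene Irf8 (-1.29 and 0.80) and the MHC class II gene H2-Aa (-1.01 and 1.47). Meox1 went the other way (0.69 and -1.23). Single genes higher on the beads, chosen after their values were seen, were Asb4, which encodes a ubiquitin ligase subunit, by 3.35 and 2.74 in Ctrl and Stat3KO, the insulin receptor substrate gene Irs4 by 2.57 and 2.17, and the homeobox gene Otp by 2.34 and 2.19. Among nuclear RNAs Snhg14 was at -2.48 and -2.26 and Rian at -1.75 and -1.70.

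In Ctrl bead-bound replicate 1, the excess over the other Ctrl bead-bound libraries equalled 13% of the supernatant level for mitochondrially encoded transcripts, 18.2% for oligodendrocyte, 27.7% for astrocyte and 21% for microglial markers; the share for oligodendrocytes was 1.4 times that for mitochondrial transcripts, so carry-over of unbound RNA at 1 share cannot be told apart from other sources with these lists. Xist ranged from 4.77 to 113 CPM over the 12 libraries, and the Y-linked Ddx3y was counted in each, at 42.4 to 134 CPM.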
